A study of Mus musculus with 8 samples.

How the data were processed

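Single-cell RNA was measured in whole pituitary glands of male C57BL/6J mice on RD (regular diet) or HFD (high-fat diet), and of male IREfl and IREPKO mice on RD. IREfl is read here as the floxed Ern1 control and IREPKO as the knockout of IRE1 in the pituitary. Glands were collected after a 16 h fast and 4 h of feeding. Libraries were made with the 10x Chromium 3' v3.1 protocol. Per the submitters' processing notes, reads were processed with kallisto on the mm10 genome, and each deposited matrix holds raw UMI counts per gene and cell barcode, with no normalization. The version of kallisto, the counting step after it, the annotation release, the cell calling, the Cre driver and the floxed exon are not given in the sources used here.

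The 8 libraries form 4 groups with 2 numbered libraries each. The numbered libraries of a group were checked for independence first. They shared between 99.6% and 99.8% of their barcodes, while libraries of different groups shared between 0 and 5. Their UMIs per shared barcode correlated with r between 0.9995 and 0.9999 on the log scale, and their gene counts differed by less than counting error, with a chi-square per gene between 0.534 and 0.732. The numbered libraries of a group therefore hold the same cells and were counted as 1 sample per group. Counts per cell were the mean of the numbered libraries over the barcodes found in both. With 1 sample per group no spread between animals could be estimated, so no test was made, no p-value is given and no genes are counted as changed. "Higher" and "lower" describe the samples measured.

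Barcodes with under 500 UMIs, under 300 genes or over 20% mitochondrial UMIs were left out. Scrublet as in scanpy 1.11.5, with an expected rate of 6%, marked 2 of the 12584 barcodes that passed, so it separated few or no doublets and doublets remain among the 12582 cells analysed. Cells were clustered on 2000 variable genes, 30 principal components and 15 neighbours with leidenalg 0.10.2 at resolution 1, after scaling to 10000 UMIs per cell and scaling each gene within each group. The genes of all gene lists, mitochondrial, ribosomal protein and haemoglobin genes and Xist were left out of the clustering.

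A cluster took the name of the class whose markers had the highest mean log2 fold against all other cells, with at least 3 markers detected. A cluster was left unnamed where that lead over the second class was below a log2 of 1, a margin that was set after the data were seen. The marker classes were somatotrope, lactotrope, corticotrope, melanotrope, gonadotrope, thyrotrope, stem/folliculostellate, pituicyte, endothelial, fibroblast, pericyte, macrophage, T/NK cell, B cell, neutrophil, erythroid and proliferating. All names are written with "-like", since they rest on transcripts alone.

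Counts were summed over the cells of a class in each group and scaled with TMM factors in edgeR 4.0.16 under R 4.3.3. Log2 ratios carry 95% intervals from the Clopper-Pearson limits of 1 count as a share of both counts. Shares of cells carry 95% Clopper-Pearson intervals, and levels of a gene in 1 group carry Poisson limits. The numbered libraries of a group shared an estimated 15.1% to 51.5% of molecules, so the limits for their mean counts are approximate. These intervals cover counting error only, not differences between animals or preparations. A ratio against 0 counts is computed with a floor of 3 counts over the group, and is not a 95% limit. Genes entered with at least 20 UMIs over the 2 groups compared, and classes with at least 50 cells in each.

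Gene lists were described by the median log2 ratio of their members, with at least 3 members, set against 10000 random lists of genes matched in expression over 20 bins. The percentile among random lists is a description, not a p-value, since members of a list are not independent. A list is called apart from random lists where its median lay outside their central 95%. The lists were pituitary hormones, receptors for hypothalamic and peripheral hormones, UPR sensors, XBP1 targets of the ER, ATF6 chaperones, PERK-ATF4 targets, RIDD substrates of IRE1, NF-kB and inflammatory genes, interferon and antigen presentation genes, immediate early and heat shock genes of tissue dissociation, granins and prohormone processing, nuclear OXPHOS genes, mitochondrially encoded genes, sterol synthesis, PPAR and fatty acid genes, thyroid hormone induced genes, oxidative stress NRF2 targets, and ribosomal proteins.

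Named genes followed a fixed rule. Over the endocrine classes, a gene needed at least 20 UMIs over both groups, at least 50 CPM (counts scaled to a common total) in 1 group in at least 3 classes, and the same direction in every one. The 10 highest and 10 lowest by median log2 ratio were taken. A few items that these rules would name are not reported here. In each endocrine class, the stem/folliculostellate-like and the macrophage-like class, the 3 highest and 3 lowest genes with at least 50 UMIs, at least 100 CPM and Poisson limits of the levels that do not overlap are named. All hormones and UPR sensors and up to 4 members per list were also taken. Genes that are named here and in no part of the rule are the marker genes that lead a cluster. The gene lists, marker lists, filters, naming rule and comparisons were fixed before the data were examined, with the margin for cluster names as the exception.

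The alternatives were DESeq2 1.42.0 size factors, CPM of all UMIs, CPM without the hormone genes, clustering at resolution 0.5, shares over endocrine cells alone, either numbered library left out, a stricter cell filter (1000 UMIs, 10% mitochondrial), cells thinned to 2000 UMIs, a minimum of 100 UMIs, no minimum, and doublet calls kept. Chosen after seeing the data were the other RD-fed control library as reference, a correction for transcript length, cells without the 6% highest doublet scores, and cells without over 5% of UMIs from hormones of other classes. Transcript lengths and gene places came from GENCODE M21 on GRCm38, which matched 55154 of the 55421 genes by ID. The length of a gene was that of its longest annotated transcript, which may not be the one expressed. The ratios and list medians were tested on simulated data made from the lactotrope-like counts. Both groups were drawn as independent Poisson counts from the same mean levels, with no difference between libraries beyond the set changes. The rates that follow therefore hold for counting error alone. A simulated 2-fold difference was recovered as a median log2 of 1.01 and 1.03 in the 2 comparisons, with an interval that excluded 0 for 84.8% and 79.6% of genes, and for 54.1% and 53.7% of genes at 1.5-fold. A list shifted by −0.5 was recovered at −0.50 and −0.46, while 4 and 2 of 50 unshifted lists lay outside the central 95%. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.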

Results

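Transcripts of single cells were counted in whole pituitary glands of male mice in 4 groups: WT_RD and WT_HFD, wild-type mice on regular or high-fat diet, and IREfl_RD and IREPKO_RD, mice on regular diet whose labels are read here as an intact and a pituitary-deleted IRE1 gene (Ern1). The unfolded protein response (UPR) relieves the endoplasmic reticulum (ER) of misfolded protein, and IRE1 is the sensor that splices the Xbp1 transcript. The numbered libraries of a group held the same cells, so each group stands for 1 sample and no value has a spread between replicates. Total UMIs of the numbered libraries were 31165577 and 30822863 in WT_RD, 20351948 and 20241007 in WT_HFD, 21459736 and 21351603 in IREfl_RD, and 27898062 and 27722993 in IREPKO_RD. The cells analysed numbered 4685, 2806, 1710 and 3381, with median UMIs per cell of 5342, 5500, 9336 and 6617. The lowest UMI total of any deposited barcode was 2261, 2277, 4130 and 2599 in the first libraries, so the IREfl_RD matrix starts at a higher level than the others, and shares of cells are compared across unlike limits.

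Somatotrope-like cells, which make growth hormone, were the largest class in the RD-fed libraries, with 33.7% of cells in WT_RD, 22.3% in IREfl_RD and 34.9% in IREPKO_RD, and 19.6% in WT_HFD, where macrophage-like cells were more. Lactotrope-, corticotrope-, melanotrope- and gonadotrope-like cells, stem/folliculostellate-like cells and macrophage-like cells made up most of the rest. Clusters left unnamed held 8.56%, 6.45%, 10.2% and 10.1% of cells. No cluster was thyrotrope-like, although cells with at least 1% of their UMIs from Tshb, the beta subunit of thyrotropin, made up 0.491%, 0.570%, 0.643% and 0.769% of cells. Several classes were built from separate clusters in WT_HFD and in the RD-fed libraries. Cluster 5 held 547 somatotrope-like cells, cluster 10 held 372 lactotrope-like, cluster 12 held 325 corticotrope-like and cluster 23 held 129 melanotrope-like cells, all from WT_HFD, and 146 of the 147 cells of stem-like cluster 19 were from WT_HFD. The RD-fed cells of these classes lay in clusters 0, 3 and 14 (somatotrope-like), 1 (lactotrope-like), 2 (corticotrope-like), 6 (melanotrope-like) and 4 (stem-like), while gonadotrope-like clusters 7 and 30 held cells of all 4 groups. Macrophage-like clusters 11, 16 and 20 held 196, 99 and 52 cells of WT_RD and 0 of WT_HFD. Clusters 8, 17, 22 and 27 held the macrophage-like cells of WT_HFD, with 40, 14, 10 and 4 cells of WT_RD. Ratios in this class thus mostly compare cells of different clusters too.

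Hormone RNA outside its own class differed between libraries. Gh took 12% of UMIs in macrophage-like cells of WT_RD, 0.612% in WT_HFD, 8.39% in IREfl_RD and 9.04% in IREPKO_RD, and 24.3%, 3.79%, 24.1% and 20.6% in stem/folliculostellate-like cells. A hormone transcript outside its own class can therefore be background, from free RNA or from the doublets that remain, which were not told apart.

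**Figure D1:**
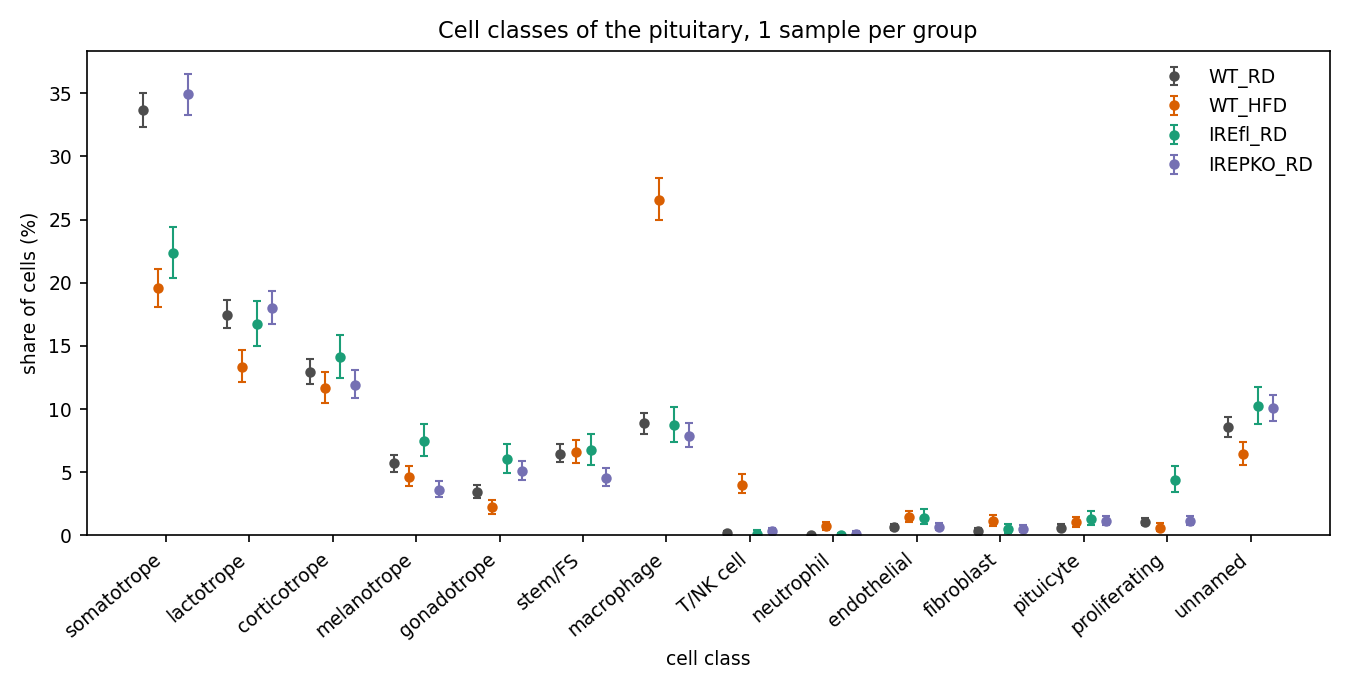
Share of cells in each class (percent of all analysed cells) in the 4 groups, as points with 95% Clopper-Pearson intervals, 1 sample per group. Macrophage-like cells lay at 26.6% in WT_HFD and between 7.90% and 8.86% in the other groups.

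The first comparison, WT_HFD against WT_RD, asks what a high-fat diet does to pituitary cells and their UPR. Macrophage-like cells were 26.6% of cells in WT_HFD (25.0 to 28.3) and 8.86% in WT_RD (8.06 to 9.71), and somatotrope-like cells 19.6% (18.1 to 21.1) and 33.7% (32.3 to 35.1). In somatotrope-like cells all 28 XBP1 targets of the ER, which serve protein import and folding, were lower in WT_HFD, with a median log2 ratio of −0.59 on the TMM scale (0.10 in CPM of all UMIs) against −0.42 to −0.10 for the central 95% of random lists. In the same cells 17 of 18 immediate early and heat shock genes and 21 of 24 interferon and antigen presentation genes were higher, with medians of 1.12 and 0.71. Gh, growth hormone, was lower there, with a log2 ratio of −1.19 (−1.19 to −1.18) and of −0.49 in CPM of all UMIs.

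Immune cells were more frequent in WT_HFD in every class found. T/NK-like cells, led by Nkg7, Cd3g and Ifng, were 4.03% of cells (3.33 to 4.82) against 0.192% (0.0879 to 0.364), a ratio of 21 (10.7 to 47.0), and macrophage-like cells had a ratio of 3.0 (2.66 to 3.39). Without cells with over 5% of hormone UMIs of other classes, the share of T/NK-like cells in WT_RD was 0.0708%, so the size of that ratio depends on a few cells. Neutrophil-like cells, led by the granule gene Camp and by S100a9, were 20 of the WT_HFD cells and 0 of the 4685 WT_RD cells, which allows a share of up to 0.0787%. Of the macrophage-like cells in WT_HFD, 353 lay in cluster 8, 181 in cluster 17 (led by Cxcl2 and Nlrp3, a chemokine and an inflammasome sensor), 120 in cluster 22 (led by the microglial genes Crybb1 and P2ry12) and 92 in cluster 27 (led by the cytokine gene Il1a). Fibroblast-like and endothelial-like cells were also more frequent, with ratios of 3.34 (1.78 to 6.52) and 2.23 (1.35 to 3.70), but endothelial-like cells differed as much between the RD-fed control libraries, with a ratio of 2.19 (1.23 to 3.88) for IREfl_RD against WT_RD.

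Endocrine cells were 51.4% of WT_HFD cells (49.6 to 53.3) and 73.3% of WT_RD cells (72.0 to 74.5). The ratio was 0.581 (0.526 to 0.641) for somatotrope-like, 0.764 (0.675 to 0.865) for lactotrope-like and 0.643 (0.472 to 0.867) for gonadotrope-like cells. For somatotrope-like cells it was 0.663 (0.592 to 0.742) between the control libraries IREfl_RD and WT_RD. Over endocrine cells alone, the share of lactotrope-like cells turned, at 26.0% in WT_HFD and 23.9% in WT_RD, while that of somatotrope-like cells stayed lower, at 38.0% and 46.0%. Over all cells the ratio was 0.899 (0.784 to 1.03) for corticotrope-like, 0.813 (0.654 to 1.01) for melanotrope-like and 1.02 (0.844 to 1.23) for stem/folliculostellate-like cells, differences that were not detectable at this depth. Over endocrine cells alone, corticotrope-like cells were 22.7% and 17.7% and melanotrope-like cells 9.01% and 7.78%.

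Among hormones, Gh gave 41.3% of the UMIs of somatotrope-like cells in WT_HFD and 58.0% in WT_RD. Prl, prolactin, gave 20.9% and 37.0% in lactotrope-like cells, with a log2 ratio of −1.29. Pomc, the precursor of ACTH and melanocortins, gave 13.6% and 13.5% in corticotrope-like cells (log2 −0.19, and 0.01 with CPM of all UMIs) and 32.0% and 24.5% in melanotrope-like cells (log2 0.39). In gonadotrope-like cells the luteinizing hormone subunit Lhb had a log2 ratio of −2.30 (−2.74 to −1.88), the common subunit Cga −0.92 and the follicle-stimulating hormone subunit Fshb 0.06 (−0.17 in cells thinned to 2000 UMIs each). Against the other RD-fed control library, IREfl_RD, Lhb and Cga in these cells lay at 0.13 and 0.42. Over all cells Tshb had a log2 ratio of 0.55. The hormone list as a whole had a median of −1.04 in somatotrope-like cells, which also counts the background of hormones of other classes.

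Because Gh and Prl took a smaller share of UMIs, scaling matters in this comparison. CPM of all UMIs lay above the TMM scale by 0.70 (log2) in somatotrope-like, 0.46 in lactotrope-like, 0.37 in stem/folliculostellate-like, 0.25 in gonadotrope-like, 0.20 in corticotrope-like, 0.02 in macrophage-like and −0.01 in melanotrope-like cells, and by 0.58 over all cells. Values and counts of members are on the TMM scale, where a gene lower by less than these shifts would be higher in CPM of all UMIs. The median of the XBP1 list in somatotrope-like cells was thus 0.10 in CPM of all UMIs, and that in lactotrope-like cells went from −0.42 to 0.043, while its distance in somatotrope-like cells from matched random lists was −0.33 with TMM and −0.34 with CPM of all UMIs.

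XBP1 targets of the ER lay below matched random lists in somatotrope-like (−0.33, 0 members higher and 28 lower), lactotrope-like (−0.24, 1 and 27), gonadotrope-like (−0.17, 8 and 20), stem/folliculostellate-like (−0.27, 7 and 21) and macrophage-like cells (−0.48, 9 and 19). They lay within random lists in corticotrope-like (0.13) and melanotrope-like cells (0.05). The direction turned in gonadotrope-like cells against IREfl_RD (0.031) and in stem/folliculostellate-like cells without cells that held over 5% of hormone UMIs of other classes (0.070). Stem/folliculostellate-like and macrophage-like cells of WT_HFD held less background of endocrine RNA, and what this adds to their list values was not measured. In somatotrope-like cells the translocon subunit Sec61g had a log2 ratio of −1.66 (−1.91 to −1.41), the translocon partner Serp1 −1.23 (−1.38 to −1.08), the COPII coat gene Sec24d −1.21 (−1.55 to −0.88) and Ostc, of the oligosaccharyltransferase, −1.11 (−1.20 to −1.03). Sec61g was also lower in lactotrope-like cells, by a log2 ratio of −1.62 (−1.93 to −1.32), and in macrophage-like cells at −1.74 (−2.27 to −1.23).

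ATF6 chaperones lay above random lists in corticotrope-like (0.20, 10 of 14 higher) and melanotrope-like cells (0.23, 12 of 14 higher), where Herpud1, a gene of ER-associated degradation, was at 0.74 (0.41 to 1.08). In macrophage-like cells Herpud1 was at 1.12 (0.96 to 1.28) and the chaperone Hspa5 (BiP) at 0.75 (0.68 to 0.82). In somatotrope-like cells the list lay within random lists (−0.21), with Manf, a secreted ER stress protein, at −0.86 (−0.95 to −0.78).

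PERK-ATF4 targets, genes of amino acid supply and the integrated stress response, lay below random lists in somatotrope-like (−0.48, 13 of 19 lower) and lactotrope-like cells (−0.34, 14 of 17 lower). The glutathione-degrading gene Chac1 had a log2 ratio of −2.45 (−3.67 to −1.43) and Vldlr, a lipoprotein receptor, −1.59 in somatotrope-like cells, while the pseudokinase Trib3 was at 1.45 (0.64 to 2.29). Against IREfl_RD the list in somatotrope-like cells lay at 0.05. The log2 ratios of the UPR sensors in somatotrope-like cells, on the TMM scale, were: Ern1 −0.78 (−1.09 to −0.48), Eif2ak3 (PERK) −0.57, Xbp1 −0.52 (−0.66 to −0.38) and Atf6 −0.15 (−0.50 to 0.21), with a list distance of −0.35 that was within random lists. Over all cells Xbp1 was at −0.49 (−0.56 to −0.42) on the TMM scale, but took 0.0145% of UMIs in WT_HFD and 0.0136% in WT_RD, and 0.0137% and 0.0121% in somatotrope-like cells. There Atf6 (0.00233% and 0.00159%) and Eif2ak3 (0.00139% and 0.00128%) also took a larger share in WT_HFD, and Ern1 a smaller one (0.00272% and 0.00288%). RIDD substrates, transcripts degraded by IRE1, lay within random lists in each class with at least 3 members measured, and above them over all cells (1.02, 6 of 7 higher), and the extracellular matrix gene Sparc is among the top genes of microglia-like cluster 22.

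**Figure D2:**
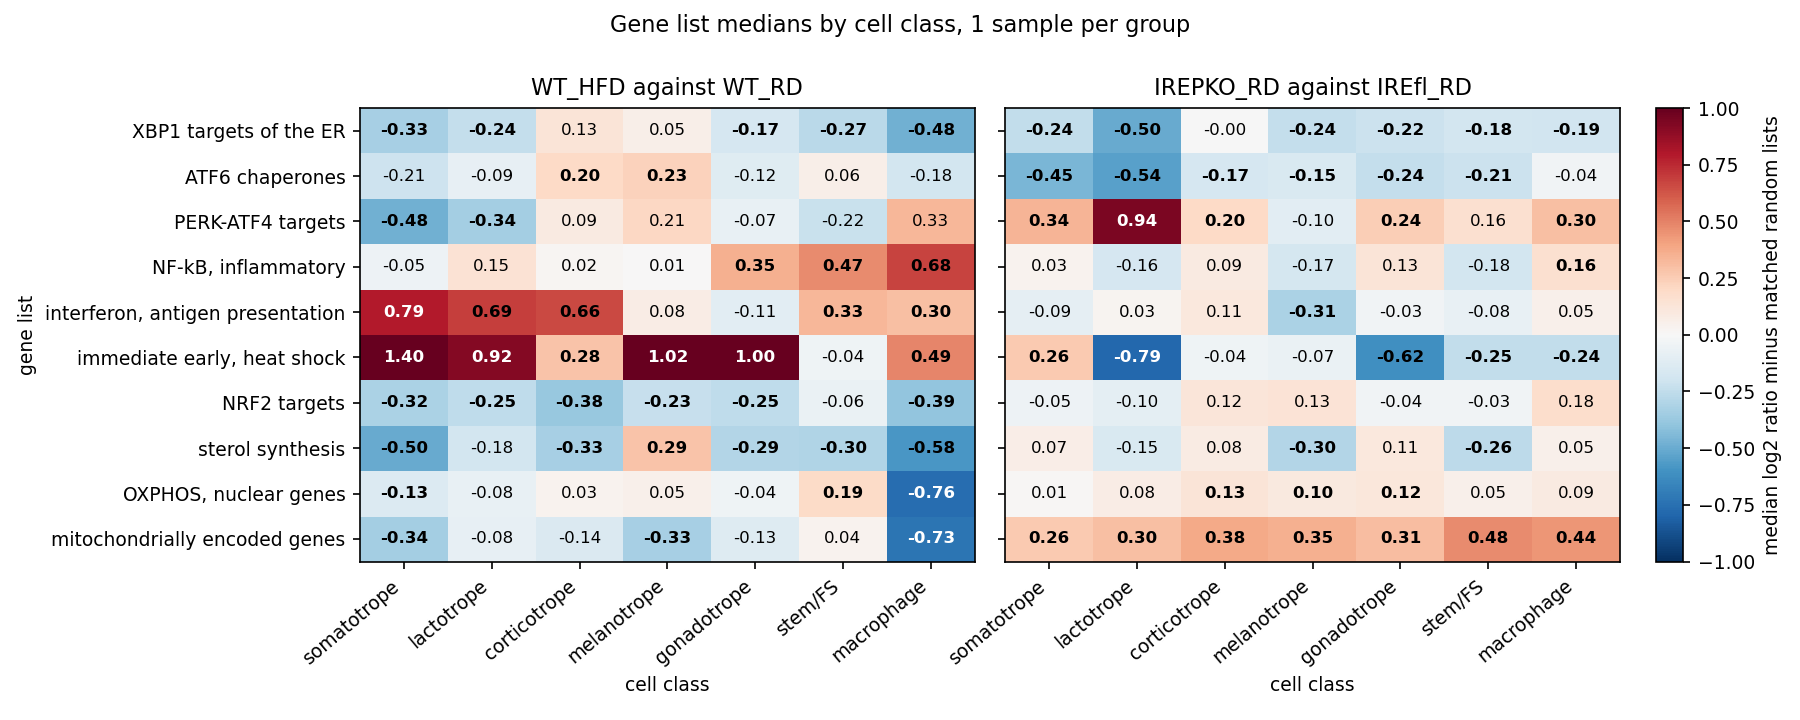
Median log2 ratio of each gene list minus that of matched random lists, by cell class and comparison, 1 sample per group. Bold values lie outside the central 95% of 10000 random lists, and colours saturate at 1.0. The XBP1 list lies at −0.50 in lactotrope-like cells of IREPKO_RD against IREfl_RD and at −0.24 in WT_HFD against WT_RD.

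Immediate early and heat shock genes, which also respond to the dissociation of tissue, lay above random lists in somatotrope-like (1.40), lactotrope-like (0.92), corticotrope-like (0.28), melanotrope-like (1.02), gonadotrope-like (1.0, 18 of 18 higher) and macrophage-like cells (0.49), and within them in stem/folliculostellate-like cells (−0.04). In somatotrope-like cells the nuclear receptor Nr4a1 was at 2.08 (1.83 to 2.34), Btg2 at 2.08 (2.01 to 2.15) and Fos at 1.62 (1.55 to 1.68). In melanotrope-like cells Atf3 was at 2.54 (1.89 to 3.24).

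Interferon and antigen presentation genes lay above random lists in somatotrope-like (0.79), lactotrope-like (0.69, 20 of 22 higher), corticotrope-like (0.66, 18 of 22, but 0.32 with a minimum of 100 UMIs), stem/folliculostellate-like (0.33) and macrophage-like cells (0.30, 23 of 25), but not in melanotrope-like (0.08) or gonadotrope-like cells (−0.11). Against IREfl_RD the value in macrophage-like cells was −0.024. The interferon-induced GTPase genes Gbp2 and Gbp3 had log2 ratios of 3.13 (2.24 to 4.13) and 1.52 (1.17 to 1.89) in somatotrope-like cells, and the antiviral gene Ifit1 1.78 (1.09 to 2.5). The immunoproteasome genes Psmb8 and Psmb9 were at 1.33 (0.93 to 1.74) and 1.28 (0.76 to 1.81) in lactotrope-like cells. NF-kB and inflammatory genes lay above random lists in macrophage-like (0.68, 16 of 17 higher), stem/folliculostellate-like (0.47) and gonadotrope-like cells (0.35). The chemokine gene Ccl7 was at 2.78 (2.11 to 3.54), Tnf at 1.46 (1.31 to 1.61) and Nfkb1 at 1.43 (1.24 to 1.64) in macrophage-like cells. Immune cells were also more frequent in the same library, and in gonadotrope-like cells the list was led by Cxcl2 (4.24, 3.51 to 5.08) and Il1b (3.31, 2.20 to 4.64), and Cxcl2 also leads macrophage-like cluster 17.

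Sterol synthesis genes lay below random lists in somatotrope-like (−0.50, 17 of 18 lower), corticotrope-like (−0.33), gonadotrope-like (−0.29), stem/folliculostellate-like (−0.30, 18 of 18 lower) and macrophage-like cells (−0.58), and above them in melanotrope-like cells (0.29, but −0.017 with a minimum of 100 UMIs). Dhcr7, Cyp51 and Fdps, enzymes of cholesterol synthesis, had log2 ratios of −1.61 (−2.15 to −1.10), −0.99 (−1.28 to −0.70) and −0.96 in somatotrope-like cells. PPAR and fatty acid genes lay above random lists in melanotrope-like (0.33), gonadotrope-like (0.36) and stem/folliculostellate-like cells (0.36, 12 of 16 higher), where Acot1, a thioesterase, was at 1.68 (1.29 to 2.09). Cd36, a fatty acid transporter, was at 2.92 (2.21 to 3.72) in macrophage-like cells. NRF2 targets of oxidative stress lay below random lists in each of the 5 endocrine classes, between −0.38 and −0.23, and in macrophage-like cells (−0.39). Against IREfl_RD, NRF2 targets turned in corticotrope-like (0.0079) and macrophage-like cells (0.13), sterol synthesis in melanotrope-like (−0.14) and gonadotrope-like cells (0.018), and PPAR genes in gonadotrope-like cells (−0.11). The metallothionein genes Mt1 and Mt2 were at −2.89 (−2.94 to −2.84) and −2.70 (−2.80 to −2.60) in corticotrope-like cells.

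Nuclear OXPHOS genes lay below random lists in somatotrope-like (−0.13, 34 of 36 lower) and macrophage-like cells (−0.76, 34 of 36 lower) and above them in stem/folliculostellate-like cells (0.19). Mitochondrially encoded genes lay below in somatotrope-like (−0.34), melanotrope-like (−0.33) and macrophage-like cells (−0.73), the last pair turning against IREfl_RD (0.13 and 0.10), with mt-Nd3 at −1.95 (−2.22 to −1.68) in somatotrope-like cells. Granins and prohormone processing genes were mostly lower in corticotrope-like cells (10 of 12, −0.20, within random lists), where the neuropeptide precursor Vgf was at −4.21 (−4.81 to −3.67) and the prohormone convertase Pcsk1 at −1.53 (−1.73 to −1.34). Their distance of −2.76 in macrophage-like cells goes with the lower background of endocrine RNA in WT_HFD. What this background adds to the OXPHOS and mitochondrially encoded values of macrophage-like cells was not measured. Receptors for hormones lay within random lists in the endocrine classes, with the receptor for growth hormone releasing hormone, Ghrhr, at −0.82 (−1.01 to −0.64) in somatotrope-like cells. Thyroid hormone induced genes lay within random lists, but at their edge in corticotrope-like cells (−0.59, percentile 2.82), where a second draw of random lists, made for the alternatives, placed them outside the central 95%, and they turned against IREfl_RD (0.035). In these cells Thrsp was at 1.33 (1.0 to 1.66) and Klf9 at −0.93 (−1.11 to −0.75).

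Ribosomal proteins lay between −0.20 and 0.03 from random lists, and outside their central 95% in melanotrope- (turning to 0.039 against IREfl_RD), stem/folliculostellate- and macrophage-like cells, but single members shifted alike in all classes. Rpl34 had a median log2 ratio over the classes of −3.25 (range −3.65 to −3.05), Rpl36a −1.57 and Rpl36 −1.22, while Rps10 was at 0.90 and Rpl3 at 0.88. Across 58 such genes the log2 ratios of any pair of classes correlated with r between 0.94 and 0.98 over 21 pairs, where genes are not independent replicates.

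Over the endocrine classes, the named genes lower in WT_HFD were led by Srxn1, an antioxidant gene (median −2.92, range −3.84 to −1.62), the cell cycle inhibitor Cdkn1a (−2.43, −3.20 to −2.39) and the TWEAK receptor Tnfrsf12a (−2.32, −2.92 to −0.71). They went on with Gm10076 (−1.94), the synaptic scaffold gene Homer1 (−1.89), Gm44510 (−1.73), the lipid droplet gene Cidea (−1.73), Kcnmb4os2 (−1.73) and the phosphatase gene Dusp14 (−1.58). For these genes WT_HFD lay closer to IREfl_RD than to WT_RD. Against IREfl_RD, Srxn1 lay at −0.56, Cdkn1a at −0.61, Tnfrsf12a at −0.25, Cidea at −0.49, Kcnmb4os2 at −0.28 and Dusp14 at −0.43, while Gm10076 (0.46), Homer1 (0.60) and Gm44510 (0.53) turned. The highest were the haemoglobin genes Hbb-bt (7.37, 5.54 to 7.41), Hba-a1 (6.77), Hba-a2 (6.67) and Hbb-bs (4.03), the RNA of red blood cells. They were followed by AC149090.1 (2.19, 1.76 to 2.89), the long noncoding RNA Snhg11 (1.72, 0.52 to 2.07), Nr4a1 (1.40), the heat shock gene Dnajb1 (1.24), Btg2 (1.23) and Fos (1.18). Their medians all stayed above 0 against IREfl_RD, at 1.79, 1.69, 0.12, 0.77, 0.33 and 0.54. The lowest class value there was below 0 for Nr4a1 (−0.35), Dnajb1 (−0.11) and Btg2 (−0.53).

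Within single classes, Vgf, Srxn1 and Zfp948 (−3.63) were lowest in corticotrope-like cells, Zdbf2 was at −1.90 in lactotrope-like cells and Id2, an inhibitor of differentiation, at 2.19 (1.73 to 2.66) in gonadotrope-like cells. Values of single genes within a class, other than hormones in their own class, were not set against the other RD-fed control in either comparison. In corticotrope-like cells Srxn1 was at 3556 CPM of all UMIs in WT_RD, 346 in IREfl_RD and 285 in WT_HFD. WT_RD thus lay apart from both, and other values of this class may share that. In melanotrope-like cells Jun was at 1.47, the small heat shock gene Hspb1 at 1.47 and Fosb at 1.34. Stem/folliculostellate-like cells of WT_HFD held 37112 UMIs of Bpifa1, a secreted airway-type protein gene, against 0 in WT_RD, or 14367-fold with the floor of 3 counts. They also held the mucosal peptide gene Tff2 (3017 UMIs against 1, log2 11.77, 9.30 to 17.08) and the thyroxine carrier gene Ttr (39997 against 14.5, log2 11.65, 10.91 to 12.50). The number of cells that held the UMIs of Bpifa1, Tff2 and Ttr was not counted, so a few cells may be their source. In macrophage-like cells Ttr was also higher (5.75, 4.19 to 8.03), but at 0.418% of its level in stem/folliculostellate-like cells, so free RNA is not excluded. These cells had higher levels of the class Ib gene H2-M2 (4.25, 3.54 to 5.07) and the elastase gene Mmp12 (3.24, 2.94 to 3.56). Tshb was higher in lactotrope-like (6.82, 6.45 to 7.21) and lower in melanotrope-like cells (−9.68, −14.99 to −7.20, 1 UMI against 779). These values go with single cells that had at least 1% of their UMIs from Tshb: 2 of WT_HFD in lactotrope-like cluster 10 and 0 of WT_RD in cluster 1, and 1 of WT_RD in melanotrope-like cluster 6 and 0 of WT_HFD in cluster 23. Without cells with over 5% of hormone UMIs of other classes, the lactotrope-like value fell to 2.10. Gal, galanin, was at 3.28 in gonadotrope-like cells but at −0.38 with doublet calls kept. Hormones of other classes that were lowest, such as Cga (−4.99), Fshb (−4.98) and Gh (−4.32) in macrophage-like cells, follow the background.

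The comparison rests on 1 sample per diet, so differences between animals, preparations and diets were not separated. Against IREfl_RD, 39 of the 51 list values outside random lists in the second draw kept their direction.

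The second comparison, IREPKO_RD against IREfl_RD, asks what loss of IRE1, as the label is read, does to the gland. Ern1, the gene of IRE1, was higher in the library labelled IREPKO_RD, with a log2 ratio of 0.54 (0.36 to 0.73) over all cells. In the first numbered libraries it was at 24.0 CPM of all UMIs (22.2 to 25.9) against 16.6 (14.9 to 18.4) in IREfl_RD, and in the second at 24.4 against 16.7. The log2 ratio was 0.49 (0.18 to 0.82) in somatotrope-like and 0.69 (0.19 to 1.20) in lactotrope-like cells. WT_RD and WT_HFD lay at 22.4 and 20 CPM in the first numbered libraries. A 3' tag can lie outside a deleted exon, so this level checks neither the deletion nor the label, and each direction below is that of the library labelled IREPKO_RD.

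XBP1 targets of the ER and ATF6 chaperones were lower, and PERK-ATF4 targets higher, in the library labelled IREPKO_RD, most of all in lactotrope-like cells. There 24 of 28 XBP1 targets were lower, with a median of −0.52 against −0.12 to 0.08 for random lists, as were 12 of 14 ATF6 chaperones (median −0.58 against −0.18 to 0.11). Of 18 PERK-ATF4 targets 15 were higher (median 0.96 against −0.13 to 0.17). The co-chaperone Dnajb9 had a log2 ratio of −1.75 (−2.04 to −1.48), and the stress transcription factor genes Atf5 and Ddit3 (CHOP) were at 1.64 (1.39 to 1.89) and 1.63 (1.36 to 1.92).

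By class, the XBP1 list lay below matched random lists in lactotrope-like (−0.50), somatotrope-like (−0.24, 23 of 28 lower), melanotrope-like (−0.24), gonadotrope-like (−0.22), macrophage-like (−0.19) and stem/folliculostellate-like cells (−0.18, 24 of 28 lower), and not in corticotrope-like cells (−0.00). In somatotrope-like cells the signal peptidase genes Spcs3 and Spcs2 had log2 ratios of −1.60 (−1.83 to −1.37) and −1.18 (−1.27 to −1.09), Edem2, of ER-associated degradation, −1.35 (−1.75 to −0.95) and Dnajb9 −1.33 (−1.50 to −1.16). ATF6 chaperones lay below in lactotrope-like (−0.54), somatotrope-like (−0.45, 11 of 14 lower), gonadotrope-like (−0.24), stem/folliculostellate-like (−0.21), corticotrope-like (−0.17) and melanotrope-like cells (−0.15), and not in macrophage-like cells (−0.04). Manf was at −1.06 (−1.14 to −0.97), Hyou1, an ER chaperone gene, at −1.05 (−1.33 to −0.77) and the disulfide isomerase Pdia6 at −0.93 (−1.03 to −0.84) in somatotrope-like cells.

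PERK-ATF4 targets lay above random lists in lactotrope-like (0.94), somatotrope-like (0.34, 16 of 20 higher), macrophage-like (0.30), gonadotrope-like (0.24) and corticotrope-like cells (0.20), and within them in melanotrope-like (−0.10) and stem/folliculostellate-like cells (0.16). The direction turned in gonadotrope-like cells when cells were thinned to 2000 UMIs each (−0.0020) and in corticotrope-like cells with no minimum of UMIs (−0.033). Trib3 had a log2 ratio of 3.24 (1.87 to 5.03), the stress protein gene Nupr1 2.53 (2.10 to 2.99), the amino acid transporter gene Slc7a5 1.81 (1.13 to 2.56) and Sesn2 1.81 (0.95 to 2.78) in lactotrope-like cells. Atf4 itself was at 0.54 (0.39 to 0.69) in somatotrope-like cells. Of the other UPR sensors, Xbp1 was at 0.06 (−0.08 to 0.20) in somatotrope-like and −0.24 (−0.44 to −0.03) in lactotrope-like cells, Atf6 at −0.75 (−1.26 to −0.25) in lactotrope-like cells and Eif2ak3 at 0.19 (−0.05 to 0.44) over all cells. The 4 sensors lay below random lists in lactotrope-like cells (−0.46, 3 of 4 lower). RIDD substrates lay within random lists in each class with at least 3 members measured, with Sparc at −0.46 (−0.92 to −0.01) in stem/folliculostellate-like cells. Against WT_RD in place of IREfl_RD, the XBP1 list of lactotrope-like cells lay at −0.58 and the ATF6 list of somatotrope-like cells at −0.21, a smaller distance than against IREfl_RD.

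**Figure D3:**
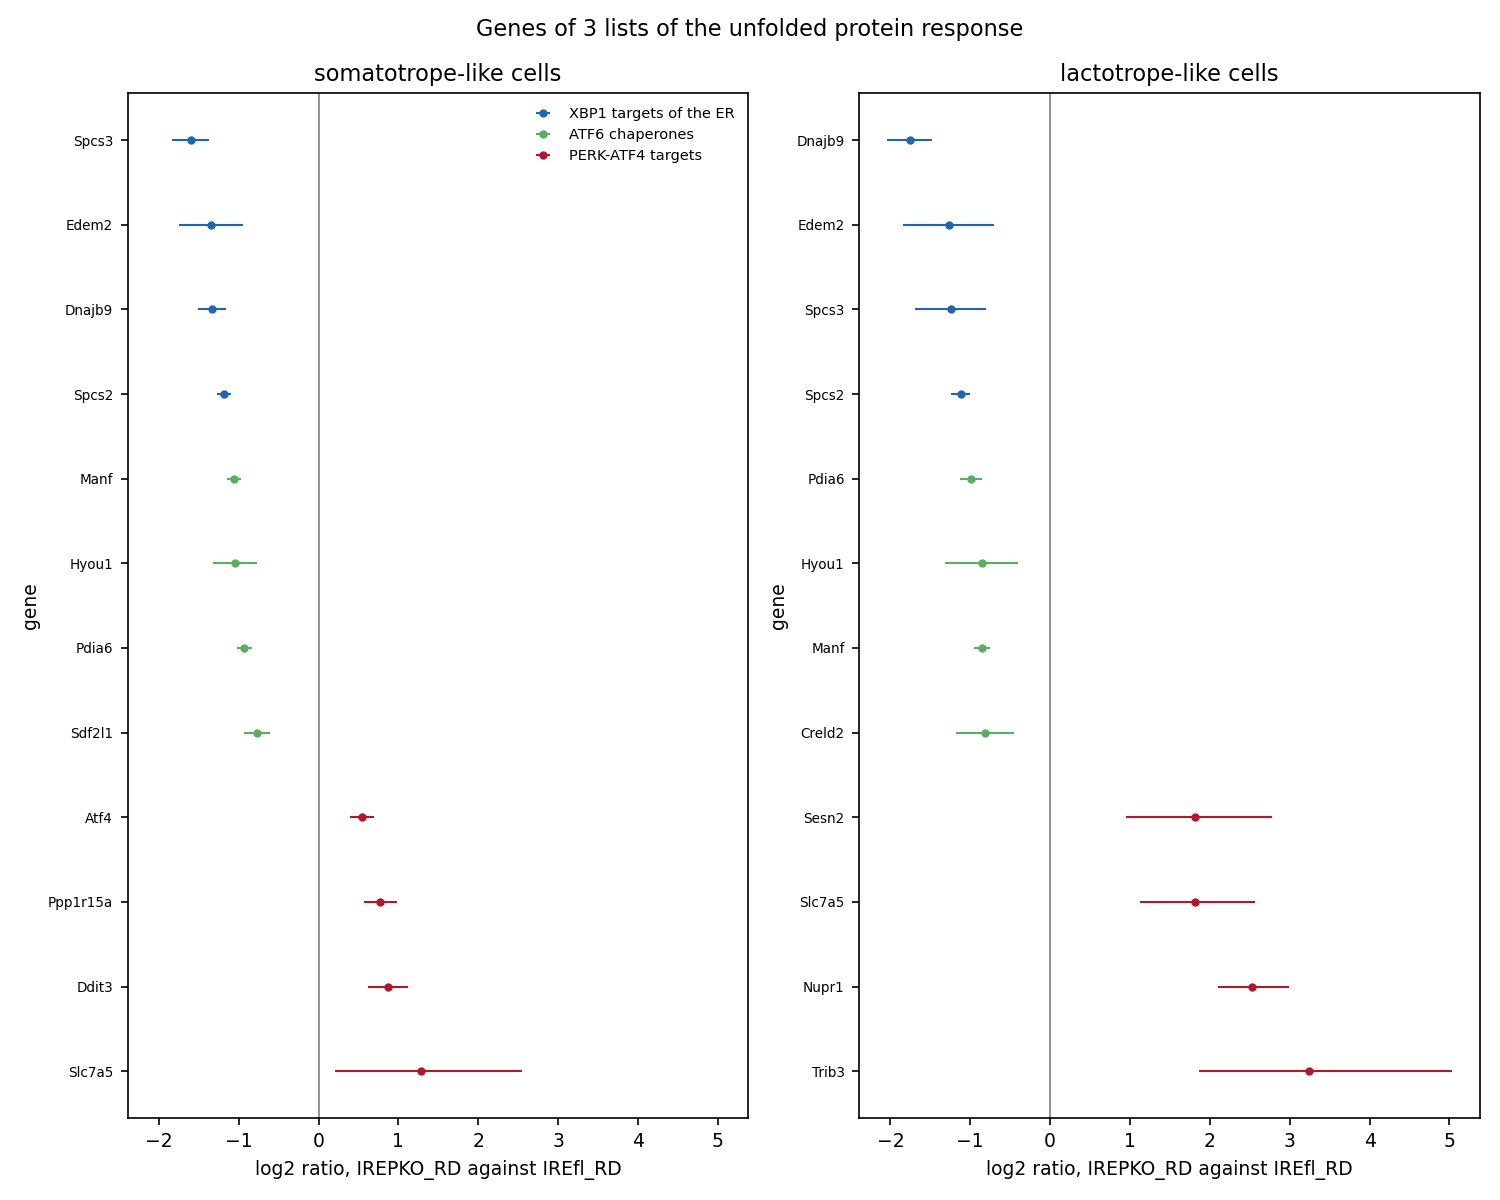
Log2 ratios of up to 4 members each of the XBP1, ATF6 and PERK-ATF4 lists in somatotrope-like and lactotrope-like cells, IREPKO_RD against IREfl_RD. Points carry 95% intervals for counting error, 1 sample per group. Trib3 lies at 3.24 and Dnajb9 at −1.75 in lactotrope-like cells of IREPKO_RD against IREfl_RD.

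Somatotrope-like cells were 34.9% of cells in the library labelled IREPKO_RD (33.3 to 36.5) and 22.3% in IREfl_RD (20.4 to 24.4), a ratio of 1.56 (1.39 to 1.76). Melanotrope-like cells were 3.61% (3.01 to 4.29) and 7.49% (6.28 to 8.84), and proliferating cells, led by Cenpf, Ube2c and Top2a, 1.15% (0.822 to 1.57) and 4.39% (3.47 to 5.47). The proliferating cluster 18 also had the haemoglobin gene Hbb-bt among its top genes. Its mean log2 fold was 5.29 for proliferating and 4.28 for erythroid markers, so this class is mixed with erythroid signal. Stem/folliculostellate-like cells had a ratio of 0.677 (0.528 to 0.870), endothelial-like 0.464 (0.248 to 0.863) and corticotrope-like 0.846 (0.719 to 0.996). The shares of lactotrope-like cells, with a ratio of 1.08 (0.933 to 1.24) that turned over endocrine cells alone (24.5% and 25.1%), and macrophage-like cells, with 0.906 (0.739 to 1.12), did not differ detectably at this depth. Between the control libraries IREfl_RD and WT_RD the ratio was 0.663 (0.592 to 0.742) for somatotrope-like and 4.11 (2.84 to 6.00) for proliferating cells, so these shares differ as much between controls. So did that of endothelial-like cells, at 2.19 (1.23 to 3.88), with 0.651% in IREPKO_RD and 0.640% in WT_RD. Between these controls melanotrope-like cells lay at 1.31 (1.06 to 1.63) and stem/folliculostellate-like cells at 1.04 (0.832 to 1.29).

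Gh and Prl differed less than between diets. Gh gave 56.7% of UMIs of somatotrope-like cells against 60.1% (log2 −0.22), Prl 43.0% of lactotrope-like cells against 46.4% (log2 −0.23) and Pomc 12.9% of corticotrope-like cells against 15.4% (log2 −0.27). Pomc was at 0.13 in melanotrope-like cells, and Lhb, Cga and Fshb at 0.71 (0.31 to 1.12), 0.52 (0.49 to 0.54) and 0.23 in gonadotrope-like cells. Over all cells Tshb was at −0.19. Against WT_RD, Prl (0.24), Pomc in melanotrope-like cells (−0.11), Lhb (−1.69), Cga (−0.81) and Fshb (−0.27) turned. CPM of all UMIs lay above TMM by between −0.03 and 0.17 in the classes.

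Mitochondrially encoded genes lay above random lists in all 7 classes, between 0.26 and 0.48, with mt-Nd3 at 1.39 (1.06 to 1.73) in somatotrope-like cells. Against WT_RD the list turned in somatotrope-like (−0.039), corticotrope-like (−0.038), melanotrope-like (−0.18) and macrophage-like cells (−0.26). Nuclear OXPHOS genes lay above random lists in corticotrope-like (0.13), melanotrope-like (0.10) and gonadotrope-like cells (0.12), with Cox6a1 at 0.49 (0.21 to 0.78) in melanotrope-like cells. Against WT_RD this list turned in corticotrope-like (−0.011) and melanotrope-like cells (−0.079). Immediate early and heat shock genes were lower in lactotrope-like (−0.79, 17 of 18 lower), gonadotrope-like (−0.62), stem/folliculostellate-like (−0.25) and macrophage-like cells (−0.24), with Junb at −1.60 (−1.81 to −1.38) and Fosb at −1.50 (−2.37 to −0.69) in lactotrope-like cells. Against WT_RD these lists turned in lactotrope-like (0.13), gonadotrope-like (0.24) and stem/folliculostellate-like cells (0.11). They were higher in somatotrope-like cells (0.26, 13 of 18 higher), where Egr1 was at 1.09 (1.0 to 1.17). Somatotrope-like cluster 14, led by Egr2, Fosb and Egr1, held 162 cells of IREPKO_RD, 27 of IREfl_RD, 80 of WT_RD and 0 of WT_HFD.

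Sterol synthesis genes lay below random lists in melanotrope-like (−0.30) and stem/folliculostellate-like cells (−0.26, 16 of 18 lower), with Insig1, a sterol sensor of the ER, at −0.82 (−1.15 to −0.49) in the latter and −1.10 (−1.48 to −0.73) in lactotrope-like cells. PPAR and fatty acid genes lay below in gonadotrope-like cells (−0.25). Against WT_RD, sterol synthesis turned in melanotrope-like (0.18) and PPAR genes in gonadotrope-like cells (0.13). Interferon and antigen presentation genes lay below in melanotrope-like cells (−0.31, but 0.023 in thinned cells), with B2m at −1.45 (−2.31 to −0.67), and within random lists in the other classes. NF-kB and inflammatory genes lay above in macrophage-like cells (0.16), where Ccl7 was at 1.86 (1.07 to 2.74) and Cxcl1 at −2.56 (−3.35 to −1.85). Receptors for hormones lay above in melanotrope-like cells (0.31, but −0.041 with no minimum of UMIs), with the thyroid hormone receptor gene Thrb at 0.74 (0.16 to 1.34) in gonadotrope-like cells. NRF2 targets lay within random lists in each class measured. So did thyroid hormone induced genes, but at the edge in somatotrope-like cells (−0.35, percentile 2.54), where the second draw placed them outside the central 95% and thinned cells turned them (0.32). Single genes were Mt1 at 0.89 (0.78 to 0.99) in somatotrope-like and Thrsp at −0.90 (−1.27 to −0.54) in gonadotrope-like cells. Granins lay below only in macrophage-like cells (−0.32), where background counts and the list turned without cells with over 5% of hormone UMIs of other classes (0.14), with Chgb at 0.92 (0.85 to 0.98) in gonadotrope-like cells. Among ribosomal proteins, whose medians lay between −0.01 and 0.11 from random lists, Rpl3 (−0.94) and Rpl7 (−0.81) were lower and Rps27 (0.87) and Rpl36 (0.82) higher over the classes. Against WT_RD this list turned in corticotrope-like (−0.058), melanotrope-like (−0.056), gonadotrope-like (−0.059) and stem/folliculostellate-like cells (−0.020).

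Of the 10 genes lowest over the endocrine classes, 9 also had a lower median against WT_RD, though Tmem38a reached 0.11 in its highest class. They were Magt1, of the oligosaccharyltransferase (median −0.93, range −2.13 to −0.78, against WT_RD −0.97), Fkbp11, an ER prolyl isomerase (−0.82, against WT_RD −1.31), the signal peptidase genes Sec11c (−0.82, −1.10) and Spcs2 (−0.80, −0.93), Dnajb9 (−0.78, −1.23), the translocon subunit Sec61b (−0.73, −0.99), Ddost, of the oligosaccharyltransferase (−0.72, −0.81), the ion channel gene Tmem38a (−0.72, −0.38) and Nucb2, the nesfatin precursor (−0.71, −0.85). Nr4a1 (−0.82) turned to 0.70. Of the 10 highest, the medians of Slirp (0.65), Gm19220 (0.62) and Ddit3 (0.62, 0.33 to 1.63) stayed above 0 against WT_RD, at 0.27, 0.03 and 0.45. The lowest class value there was below 0 for Slirp (−0.07) and Gm19220 (−0.11). Gm10076 (1.10), Rab26os (0.86), Atp5md (0.66), Tmem130 (0.62), Atp5k (0.60), Alkbh1 (0.60) and Zcchc7 (0.59) turned.

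Within single classes, the cell cycle inhibitor Cdkn1c was at −1.09 (−1.31 to −0.88) and Tshb at 2.29 (2.09 to 2.49) in gonadotrope-like cells. Cells with at least 1% of their UMIs from Tshb numbered 8 in cluster 7 and 1 in cluster 30 of IREPKO_RD, against 1 in cluster 7 of IREfl_RD, so the Tshb value goes with a few cells. In the same class the cilium genes Ccdc153 (0.5 UMIs against 168) and Tmem212 (0 against 138, log2 −5.78 with the floor of 3 counts) were lower. How many of the 103 cells of IREfl_RD held these UMIs was not counted, so a few cells or doublets may be their source. Corticotrope-like cells had lower Dynlt1b (−0.81), Tnnt1 (−0.78) and Ppia (−0.65), and melanotrope-like cells higher C2cd4b (0.89). Haemoglobin genes were among the highest in somatotrope-like (Hba-a1 6.52), corticotrope-like (Hba-a1 6.58) and macrophage-like cells (Hbb-bt 6.68) and the lowest in stem/folliculostellate-like cells (Hbb-bs −6.17). At resolution 0.5, Hba-a1 in somatotrope-like cells turned to −0.49. Prl in somatotrope-like cells was lower (−1.77), as it was in macrophage-like cells, at 2.23% of UMIs against 5.34%. Pomc was lower in somatotrope-like (−2.23) and lactotrope-like cells (−2.66), the latter at 0.11 without the highest doublet scores, while in macrophage-like cells it took 0.408% against 0.392%. Tshb was lower in melanotrope-like (−6.59) and macrophage-like cells (−3.72), where melanotrope-like cluster 6 and macrophage-like cluster 17 each held 1 cell of IREfl_RD and 0 of IREPKO_RD with at least 1% of UMIs from Tshb. Cga was lower in both (−5.08 and −1.77), the latter at 2.36 without cells with over 5% of hormone UMIs of other classes.

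The comparison rests on 1 sample per genotype, and the Ern1 level leaves the label unchecked. Against WT_RD, 29 of the 44 list values outside random lists in the second draw kept their direction.

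The comparisons were also set side by side. Across genes their log2 ratios had a Pearson r of 0.197 and a Spearman rho of 0.0122 in somatotrope-like (6022 genes), −0.175 and −0.0611 in lactotrope-like (3697 genes), −0.0301 and −0.232 in corticotrope-like, 0.260 and −0.223 in melanotrope-like, −0.251 and −0.112 in gonadotrope-like, −0.0434 and −0.0486 in stem/folliculostellate-like and 0.0822 and 0.0697 in macrophage-like cells, where genes are not independent replicates. The XBP1 list was low in both in somatotrope-, lactotrope-, gonadotrope-, stem/folliculostellate- and macrophage-like cells, while the PERK-ATF4 list was low in WT_HFD and high in IREPKO_RD in somatotrope- and lactotrope-like cells. Of these, the WT_HFD values turned against IREfl_RD for the XBP1 list in gonadotrope-like (0.031) and the PERK-ATF4 list in somatotrope-like cells (0.050), and without cells with over 5% of hormone UMIs of other classes for the XBP1 list in stem/folliculostellate-like cells (0.070). On GRCm38, Ern1 (ENSMUSG00000020715.9) lies on chromosome 11 from 106394650 to 106487852, Xbp1 (ENSMUSG00000020484.19) on chromosome 11 from 5520659 to 5525893, Dnajb9 (ENSMUSG00000014905.4) on chromosome 12 from 44205559 to 44210326, Gh (ENSMUSG00000020713.6) on chromosome 11 from 106300271 to 106301865 and Srxn1 (ENSMUSG00000032802.8) on chromosome 2 from 152105516 to 152111376.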

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

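The tests in this part were chosen after the data were seen. For the sum of Rpl34 and its pseudogene and for the length correction of the XBP1 list, the bounds were set before the tested value was seen, and for the others after.

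XBP1 targets were lower and PERK-ATF4 targets higher in the library labelled IREPKO_RD. In lactotrope-like cells length of the longest annotated transcript, IREfl_RD alone and a shift of the whole library, alike in every class, are argued against as the only source. After the median of genes of like transcript length was taken off, the XBP1 list lay at −0.54 (−0.91 to −0.35). Against WT_RD in place of IREfl_RD it lay at −0.58 from random lists. The log2 ratios of its members were lower than those in macrophage-like cells by −0.35 (−0.57 to −0.22). The intervals are bootstraps over list members, which are not independent. A difference in preparation that is uneven over classes is not excluded. In somatotrope-like cells the difference in log2 ratio from macrophage-like cells was −0.077 (−0.27 to 0.06) for the XBP1 list and 0.19 (−0.37 to 0.70) for PERK-ATF4 targets, so a shift of the whole library stays open there for these lists, while ATF6 chaperones, at −0.39 (−0.63 to −0.12), fell beyond such a shift. In corticotrope-like cells the difference was 0.092 (0.00016 to 0.19) for the XBP1 list, in the other direction, and −0.021 (−0.80 to 0.35) for PERK-ATF4 targets. Loss of IRE1 stays open as an untested hypothesis, since there is 1 library per genotype and Ern1 itself was higher in that library.

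Macrophage-like and other immune cells were more frequent in WT_HFD. Blood left in the tissue may add to them. Barcodes with under 300 genes, mostly haemoglobin RNA in WT_HFD, were 8.78% of barcodes there and 0.529% in WT_RD. The resident microglia-like clusters, which blood does not hold, were also a larger share, at 4.28% (3.56 to 5.09) against 2.33% (1.91 to 2.80) in WT_RD. In IREfl_RD they were 2.22% and in IREPKO_RD 2.34%. That bears on microglia-like cells alone, and a lower share of endocrine cells would raise it too. Blood as the source of the other immune cells is thus not excluded. A loss of endocrine cells alone would raise all other classes alike, yet stem/folliculostellate-like cells had a ratio of 1.02 (0.844 to 1.23) where macrophage-like cells had 3.0 (2.66 to 3.39). Fibroblast-like and endothelial-like cells, at 3.34 (1.78 to 6.52) and 2.23 (1.35 to 3.70), had intervals that hold the macrophage-like ratio. Pituicyte-like cells lay at 1.67 (0.963 to 2.90), so not every class argues against such a loss. The diet and the preparation of that 1 library cannot be told apart, since there is 1 library per diet.

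Ribosomal protein transcripts shifted alike in every class in each comparison. The RD-fed controls differed at these genes as well. In lactotrope-like cells the standard deviation of their log2 ratios was 0.75 for IREfl_RD against WT_RD. It was 0.45 for IREPKO_RD against IREfl_RD and 0.66 for WT_HFD against WT_RD. Shifts of this size thus also occur between control libraries on the same diet. In WT_HFD, reads of Rpl34 and of its pseudogene Rpl34-ps1 were split, with 135 and 175 CPM of all UMIs against 971 and 0.0162 in WT_RD, but their sum still had a log2 ratio of −2.14 (−2.22 to −2.06) in somatotrope-like cells, so the split may explain only part of it. Whether WT_HFD was counted with another index than the other libraries was not tested, and if so it would bear on other genes of that comparison. Loss of IRE1 is argued against as the only source, because the shifts of the 2 comparisons, which share no library, correlated across ribosomal protein genes with r = −0.66 in lactotrope-like cells. A part played by it is not excluded. In IREPKO_RD against IREfl_RD, transcript length cannot be told apart from other differences between libraries, since rho with the log2 ratio was −0.41 in lactotrope-like cells, between the values that would exclude it and require it. In WT_HFD against WT_RD rho was 0.20 (−0.03 to 0.41) in lactotrope-like cells and between 0.06 and 0.22 over the classes. This does not decide on length, since the longest annotated transcript may not be the one expressed. For Rpl34 it had 1232 bases, against 354 for the processed pseudogene.

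Barcodes with under 300 genes, which no comparison used, made up 8.78% of WT_HFD barcodes (7.81 to 9.83), against 0.529% in WT_RD, 1.38% in IREfl_RD and 1.51% in IREPKO_RD, and haemoglobin gave a median of 96.8% of their UMIs in WT_HFD. Unnamed cluster 24, led by Igkc, Cd209a and Ccr7, genes of B cells and dendritic cells, held 1.96% of WT_HFD cells, with 55 cells against 20 in WT_RD, 19 in IREfl_RD and 29 in IREPKO_RD. Unnamed cluster 28, led by Plac8 and Clec4e, genes of monocytes, held 2.35% of WT_HFD cells, with 66 cells against 9, 4 and 8. The immediate early list was lower in lactotrope-like cells (median −0.80) and higher in somatotrope-like cells (0.24) of IREPKO_RD against IREfl_RD, a difference between classes that was not tested.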

How the results depend on the processing

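The values against the other RD-fed control library, without the highest doublet scores, without cells that hold hormones of other classes, and after a length correction were chosen after seeing the data. The other alternatives were fixed before. No paired analysis was possible because each group holds 1 sample. The tests of changed genes, with their filter and replicate terms, were not run for the same reason, and leaving out a numbered library gives no value for shares, since both hold the same cells. Depth sets how many genes of a list enter: for NF-kB genes in WT_HFD and WT_RD, 8 had enough UMIs in gonadotrope-like and 17 in macrophage-like cells.

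For the distance of a list from random lists, a change of scaling moves all genes alike and cancels, and leaving out a numbered library keeps the same cells, so these settings say nothing on stability. Of the 51 list values outside random lists in WT_HFD against WT_RD, 50 kept their direction with a minimum of 100 UMIs, and 51 with no minimum, in cells thinned to 2000 UMIs each and at resolution 0.5. Of the 44 in IREPKO_RD against IREfl_RD, 44 did with a minimum of 100 UMIs and at resolution 0.5, 42 with no minimum and 41 in thinned cells. The median of a list itself can turn with scaling, as the XBP1 list did in WT_HFD in CPM of all UMIs, at 0.10 in somatotrope-like and 0.043 in lactotrope-like cells. Of 49 genes and hormones within a class in WT_HFD, 1 turned in CPM of all UMIs, 1 in thinned cells and 0 at resolution 0.5. In IREPKO_RD 0 of 49, 0 of 45 and 2 of 47 did. In these 3 settings 0 of the 19 and 0 of the 20 genes named over the endocrine classes turned. Gh in somatotrope-like cells, WT_HFD against WT_RD, stayed lower: −1.19 with DESeq2 size factors, −0.97 in CPM without hormone genes, −0.49 in CPM of all UMIs, −1.18 to −1.18 without either numbered library, −1.16 with doublet calls kept, −1.24 in thinned cells, −1.21 at resolution 0.5, −1.14 without the highest doublet scores, −1.16 without cells with foreign hormones and −1.20 against the other control. The size of the Gh difference depends on the scaling, since Gh itself takes much of the total.

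Among the alternatives, the choice of control library turned the most list values and named genes. In WT_HFD against IREfl_RD, list distances from random lists turned for PERK-ATF4 targets in somatotrope-like cells (0.050), for thyroid hormone induced genes (0.035) and NRF2 targets (0.0079) in corticotrope-like cells, and for mitochondrially encoded genes (0.13), sterol synthesis (−0.14) and ribosomal proteins (0.039) in melanotrope-like cells. They also turned for XBP1 targets (0.031), sterol synthesis (0.018) and PPAR genes (−0.11) in gonadotrope-like cells, and for interferon genes (−0.024), mitochondrially encoded genes (0.10) and NRF2 targets (0.13) in macrophage-like cells. Gm10076 (0.46), Homer1 (0.60), Gm44510 (0.53), Lhb (0.13) and Cga (0.42) turned too. The cause was not tested.

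In IREPKO_RD against WT_RD, XBP1 targets lay at −0.39 and ATF6 chaperones at −0.21 in somatotrope-like cells, and PERK-ATF4 targets at 1.16 in lactotrope-like cells, in the same direction. Mitochondrially encoded genes turned in somatotrope-like (−0.039), corticotrope-like (−0.038), melanotrope-like (−0.18) and macrophage-like cells (−0.26). Immediate early genes turned in lactotrope-like (0.13), gonadotrope-like (0.24) and stem/folliculostellate-like cells (0.11), and ribosomal proteins in corticotrope-like (−0.058), melanotrope-like (−0.056), gonadotrope-like (−0.059) and stem/folliculostellate-like cells (−0.020). OXPHOS genes turned in corticotrope-like (−0.011) and melanotrope-like cells (−0.079), sterol synthesis in melanotrope-like (0.18) and PPAR genes in gonadotrope-like cells (0.13). Nr4a1 (0.70), Gm10076 (−1.30), Rab26os (−0.26), Atp5md (−0.69), Tmem130 (−0.027), Atp5k (−0.41), Alkbh1 (−0.15) and Zcchc7 (−0.20) turned, as did Prl in lactotrope-like (0.24), Pomc in melanotrope-like (−0.11), and Lhb (−1.69), Fshb (−0.27) and Cga (−0.81) in gonadotrope-like cells. The cause was not tested.

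Other settings turned single values, and the cause was not tested. With a minimum of 100 UMIs, sterol synthesis in melanotrope-like cells lay at −0.017 and interferon genes in corticotrope-like cells at 0.32 in WT_HFD. With no minimum, PERK-ATF4 targets in corticotrope-like (−0.033) and receptors in melanotrope-like cells (−0.041) turned in IREPKO_RD. In thinned cells, thyroid hormone induced genes in somatotrope-like (0.32), interferon genes in melanotrope-like (0.023) and PERK-ATF4 targets in gonadotrope-like cells (−0.0020) turned in IREPKO_RD, and Fshb lay at −0.17 in WT_HFD. In CPM of all UMIs, Pomc in corticotrope-like cells lay at 0.0099 in WT_HFD. At resolution 0.5, Hba-a1 (−0.49) and Hbb-bs (−0.61) in somatotrope-like cells turned in IREPKO_RD, and the share of somatotrope-like cells there was 33.2%. Gal in gonadotrope-like cells of WT_HFD lay at −0.38 with doublet calls kept and at −0.60 without the highest doublet scores, where Pomc in lactotrope-like (0.11) and Hbb-bs in melanotrope-like cells (1.22) turned in IREPKO_RD. Without cells with foreign hormones, XBP1 targets in stem/folliculostellate-like cells lay at 0.070 in WT_HFD, and ribosomal proteins in gonadotrope-like (−0.0013), granins (0.14) and Cga (2.36) in macrophage-like cells turned in IREPKO_RD.

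Some comparisons of shares turned. Over endocrine cells alone, lactotrope-like cells were 26.0% in WT_HFD and 23.9% in WT_RD, corticotrope-like cells 22.7% and 17.7% and melanotrope-like cells 9.01% and 7.78%, where all were lower in WT_HFD over all cells, and lactotrope-like cells were 24.5% in IREPKO_RD and 25.1% in IREfl_RD. Stem/folliculostellate-like cells turned at resolution 0.5 (6.74% in WT_HFD, 6.81% in WT_RD) and, as little, without the highest doublet scores. Unnamed cells turned without the highest doublet scores (5.99% in WT_HFD, 5.93% in WT_RD), and in IREPKO_RD and IREfl_RD at resolution 0.5 (8.81% and 8.30%) and with doublet calls kept. Without cells with foreign hormones, WT_RD held 0.0708% T/NK-like, 7.86% macrophage-like and 36.9% somatotrope-like cells, and IREPKO_RD 37.9% somatotrope-like cells. Without the highest doublet scores somatotrope-like cells were 35.6% in WT_RD and 37.0% in IREPKO_RD. Over endocrine cells alone, somatotrope-like cells were 46.0% in WT_RD, 38.0% in WT_HFD, 33.5% in IREfl_RD and 47.5% in IREPKO_RD.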

Other observations

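Markers of cell types outside the endocrine lineages had medians above 0 over the whole gland in WT_HFD against WT_RD. Not every marker was higher for pericytes (4 of 6), fibroblasts (5 of 6) and B cells (3 of 4). The median log2 ratio was 6.00 for neutrophil, 4.27 for erythroid, 3.34 for T/NK cell, 2.75 for B cell, 1.80 for endothelial, 1.59 for fibroblast, 1.34 for macrophage, 0.90 for pericyte, 0.69 for pituicyte and 0.54 for stem/folliculostellate markers. Endocrine markers lay at 0.39 (corticotrope), 0.36 (melanotrope), 0.35 (thyrotrope), −0.21 (lactotrope), −0.42 (gonadotrope) and −2.01 (somatotrope), and proliferation markers at −0.56. In IREPKO_RD against IREfl_RD the medians were 7.91 for neutrophil (3 of 5 markers higher, with 128.5 UMIs of all 5 in IREfl_RD), 0.49 for T/NK cell, 0.31 for fibroblast, 0.30 for pituicyte, 0.21 for somatotrope, 0.20 for erythroid, 0.09 for gonadotrope and 0.07 for thyrotrope markers. They were −0.23 for B cell, −0.28 for macrophage, −0.29 for stem/folliculostellate, −0.33 for lactotrope, −0.35 for pericyte, −0.55 for corticotrope, −0.62 for endothelial, −0.90 for melanotrope and −0.93 for proliferation markers.

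Some unnamed clusters held cells of the RD-fed libraries alone. Cluster 9, led by Tshb and Gal, held 171 cells of WT_RD, 80 of IREfl_RD, 148 of IREPKO_RD and 0 of WT_HFD, and cluster 13, led by AW551984 and Tshb, 126, 45, 100 and 0. Of the cells in cluster 9, only 5, 5 and 7 of these RD-fed groups had at least 1% of UMIs from Tshb. WT_HFD held 16 such cells in other clusters. Median UMIs per cell in clusters 9 and 13 were 2.32 and 1.89 times the library median, so doublets are not excluded. Cluster 15, led by Gm42583 and the noncoding RNA Meg3, held 75 cells of WT_RD, 60 of WT_HFD, 27 of IREfl_RD and 55 of IREPKO_RD. Neutrophil-like cells numbered 5 in IREPKO_RD and 0 in IREfl_RD.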
